A study of Homo sapiens with 12 samples.

How the data were processed

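RNA was measured in 12 libraries of MCF-12A cells, 6 treated with TGFbeta1 and 6 controls. Total RNA was extracted with Trizol and made into libraries by a standard Illumina procedure, per the labels. The submitters' processing notes name FastQC, cutadapt, HISAT2 2.0.4, StringTie 1.2.3 and the genome build hg19. Their settings, strandedness and the annotation release are not given in the sources used here.

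The authors deposited FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) per protein-coding transcript in 2 tables, named here the first set (replicates 1 to 3 of each group) and the second set (replicates 4 to 6). In the second set the headers of the group means name FPKM, while those of the library columns name no unit. The group means equal the mean log2(FPKM + 1) of the library columns, which were therefore taken as FPKM. The first set's headers name no unit, and FPKM was taken from its values and from StringTie's output, so the unit of that set is inferred. For the second set the authors also deposited group means and a log2 fold change of FPKM + 1, a linear fold change, and p-values and q-values per transcript. These serve only where the authors' deposited table is named. Its log2 fold change was equal, within 1e-07, to the difference of group means recomputed from the library columns. The first set lists 44112 transcripts of 13410 genes and the second 29204 transcripts of 11504 genes, and 23335 transcripts and 11326 genes are in both. The lowest mean FPKM of a listed transcript was 0.025 in the first set and 0.250 in the second, so low transcripts were filtered at different levels before deposit. Every change was therefore taken within a set, and levels are compared across the sets only for the controls, in 1 test of the closing section. Because FPKM divides by each library's own total, a change in a few abundant genes shifts all others, and no counts were used, so depth and counting error are unknown. No library was identical to another.

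Transcripts were summed per gene symbol, with 163 symbols of the first set renamed to the second set's through the shared transcript identifiers. Genes with a mean FPKM of at least 1 over the libraries in the fit were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), using empirical Bayes with a mean-variance trend and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plotted with matplotlib 3.10.9. An FPKM of 0 can be a failed assignment: the mitochondrial gene MT-ND2 is listed at 0 in controls of the first set. Such genes are given per library. Summing to genes hides exchanges between transcripts, and assignment of reads between similar transcripts or paralogs (such as SERPINB3 and SERPINB4, or the AKR1C, S100A, keratin and histone families) can move FPKM from 1 to another.

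The comparisons were control against TGFbeta1 in the first set, in the second set, over both sets with the set as a term, and the interaction of set and agent, together with the overlap of calls between the sets. Designs, alternatives and 31 gene lists from general knowledge were fixed before the data were examined. The noncoding RNA list had no member in these protein-coding tables and was not tested. The other 30 were tested with limma's camera (preset correlation 0.01, and an estimated correlation) and with fry, where at least 3 members passed the filter, and counts were also adjusted over the list alone. The rule for named genes took the 10 largest calls in each direction over both sets with the same direction in each, the 5 largest in each direction in each set and for the interaction, the 3 members of each list with the smallest p over both sets, and 22 genes of the TGFbeta response whatever their result. Some of the 140 genes that the rule names are not reported here. The alternatives were a pseudocount of 0.1, no filter or a minimum of 5 FPKM, 3 other scalings (median of ratios, an equal sum per library, quantile normalisation), limma without trend or with robust variance, a log2 change of at least 1, leaving out each library, and the replicate number as a block. Gene sums over transcripts in both sets, tests per transcript and set tests of the interaction were added after seeing the data. Where leaving out a library left 2 in a group, the spread was pooled over groups.

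The procedure was tested on simulated data made from the real gene means and residual spreads with 100 genes changed by each of 2 sizes. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, and the change was added on that scale. Recovery of lower genes, or with many more genes changed, was not tested. For the fit over both sets the same change was added to each set. Its shares therefore do not cover genes whose effect differs between the sets, a difference that adds to the spread in the real fit. At a true log2 change of 1 it recovered 62% of changed genes in the first set (10454 genes), 80% in the second (10579 genes), 86% over both (10548 genes) and 60% for the interaction (10548 genes). At a true change of 2 the shares were 86%, 89%, 97% and 82%. Of the calls, 8.6%, 7.1%, 1.6% and 12.9% were false. Coordinates are hg19, as the files give them, and no other build was used.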

Results

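RNA-seq was carried out on MCF-12A, an established non-tumour epithelial line from human breast. Cells had received TGFbeta1, a secreted cytokine that is widely used to induce an epithelial-mesenchymal transition in epithelial cells, or vehicle as the control. The question was which transcripts TGFbeta1 changes. There were 6 control and 6 TGFbeta1 libraries, deposited as 2 separately normalised sets. The first set held replicates 1 to 3 of each group and the second set held replicates 4 to 6. Dose and duration of the treatment are not given in the labels used here. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values were FPKM per protein-coding transcript, summed here per gene. No counts were used, so the depth of each library is unknown. FPKM summed to between 291801.6 and 318269.5 per library in the first set and to between 338968.0 and 358432.6 in the second. Per library, between 10242 and 10289 genes in the first set and between 10467 and 10518 in the second reached an FPKM of 1. Across genes, log2 levels correlated between libraries of 1 group at r = 0.949 to 0.955 in the first set, and between control and TGFbeta1 libraries at 0.905 to 0.909. In the second set the ranges overlapped, at 0.968 to 0.972 and 0.965 to 0.970. Genes are not independent replicates, and these r describe similarity between libraries only.

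In the first set, TGFbeta1 libraries had higher levels of direct TGFbeta target genes, matrix genes, integrins and mesenchymal markers, and lower levels of epithelial junction genes and epidermal differentiation genes. With an estimated correlation the set test's call was lost for matrix genes (adjusted p = 0.0638) and for epidermal differentiation genes (adjusted p = 0.0662). ITGB6, the integrin subunit whose complex activates latent TGFbeta, rose from 5.54 ± 0.974 to 83.2 ± 2.27 FPKM (SD, n = 3; log2 change 3.70, SE 0.12, adjusted p = 6.7e-05). The largest rises also included the metalloprotease ADAM19, from 2.22 ± 0.933 to 56.6 ± 0.333 FPKM, the collagen gene COL5A1, from 1.91 ± 0.398 to 31.7 ± 0.404, and the transglutaminase TGM2, from 5.76 ± 1.41 to 86.2 ± 4.85 (SD, n = 3 each). AMTN was listed at 0.114, 0.173 and 0 FPKM in the controls and at 16.4, 19.1 and 12.9 with TGFbeta1 (log2 change 3.95). The largest falls were those of the keratin KRT13, the surface protein gene PSCA, the secreted iron-binding protein gene LCN2, the calcium-binding protein gene S100P and the protease inhibitor A2ML1. KRT13 was listed at 208, 203 and 292 FPKM in the controls and at 0.082, 0 and 0.425 with TGFbeta1 (log2 change -7.65, adjusted p = 4.8e-05). LCN2 fell from 93.2 ± 1.96 to 0.727 ± 0.070 FPKM and A2ML1 from 90.2 ± 4.03 to 1.76 ± 0.071 (SD, n = 3; log2 changes -5.77 and -5.05). PSCA had a log2 change of -6.90 (SE 0.81, adjusted p = 0.0037), with 105 FPKM in control 1 against 550 and 649.9 in controls 2 and 3. S100P had a log2 change of -5.73 and was listed at 2.98, 5.23 and 0 FPKM with TGFbeta1.

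On hg19, per the files, ITGB6 (ENSG00000115221.10_1) lies on chromosome 2, 160956177 to 161056824. FN1 (ENSG00000115414.18_2) lies on chromosome 2, 216225163 to 216300895. KRT13 (ENSG00000171401.14_1) lies on chromosome 17, 39657233 to 39661957. LCN2 (ENSG00000148346.11_1) lies on chromosome 9, 130911350 to 130915734. These spans run from the lowest start to the highest end of the listed protein-coding transcripts, and the values are sums over those transcripts.

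Among 21 tested TGFbeta feedback and direct target genes, 15 rose and none fell (16 and 0 adjusted over the list alone), with a median log2 change of 1.06. They included the inhibitory SMAD gene SMAD7, from 1.22 ± 0.189 to 4.35 ± 0.588 FPKM, the matrix protein gene TGFBI, from 103 ± 18.6 to 486 ± 47.2, and the ubiquitin ligase gene SMURF1, from 12.3 ± 0.381 to 24.2 ± 0.272 (SD, n = 3; adjusted p = 0.00199, 0.000506 and 0.000576). Of 19 ligand, receptor and SMAD genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The gene that fell was the ligand gene TGFB2 (log2 change -1.39), while the receptor gene BMPR2 rose by 0.76. Without a filter on low values the ligand list's adjusted p was 0.0564 against 0.00861 with it, and with an estimated correlation the adjusted p was 0.1296. ID1 and ID3, inhibitors of basic helix-loop-helix transcription factors, fell by 0.84 and 0.49 on the log2 scale. With MYC, 3 of the 5 tested genes of the ID family and MYC list fell (3 adjusted over the list alone). MYC had a log2 change of -0.81 (adjusted p = 0.0496) and kept its call without control 2 but not without any other library (adjusted p of 0.114 to 0.126). MYC also lost its call in 9 of 10 other settings, among them all 3 other scalings (adjusted p of 0.0617 to 0.0682).

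Of 16 mesenchymal markers, 12 rose and 1 fell (13 and 2 adjusted over the list alone). The fibronectin gene FN1 rose from 26.7 ± 2.43 to 214 ± 13.2 FPKM (SD, n = 3; log2 change 2.96, adjusted p = 6.7e-05), the matrix glycoprotein gene TNC by 2.90 and N-cadherin (CDH2) by 0.98. Vimentin (VIM) rose from 349 ± 65.8 to 637 ± 51.9 FPKM (log2 change 0.88, adjusted p = 0.0123). S100A4 fell by 1.16. Of 24 collagen and matrix genes, 21 rose and none fell (22 and 0 adjusted over the list alone), with a median of 1.18. Among them were COL1A1, from 1.1 ± 0.124 to 12.2 ± 1.24 FPKM, the collagen VIII chain gene COL8A1, from 6.34 ± 1.07 to 16.4 ± 1.35, and the collagen cross-linking enzyme LOXL2, from 4.29 ± 1.21 to 15.1 ± 1.76 (SD, n = 3). Of 8 integrin genes 7 rose (7 adjusted over the list alone), including ITGAV (1.69), ITGA2 (1.22) and ITGB1 (0.95). Of 21 contractile and actin cytoskeleton genes 12 rose (15 adjusted over the list alone), including SMTN (1.74), PDLIM7 (1.15) and LIMA1 (0.76). Of 5 stromal fibroblast markers 4 rose (4 adjusted over the list alone), namely COL1A1, DCN, the serine protease gene FAP (2.44) and the surface glycoprotein gene PDPN (3.20). COL1A1 and DCN are also in the collagen list and FAP in the mesenchymal list, and the DCN call was lost without TGFbeta1 3 (adjusted p = 0.0509). Of 20 secreted proteases and inhibitors 10 rose and 5 fell (10 and 5 adjusted over the list alone). The urokinase gene PLAU rose from 27.6 ± 7.67 to 261 ± 3.08 FPKM and its receptor gene PLAUR by 1.78. MMP9 was listed at 0.025, 0 and 0 FPKM in the controls and at 5.33, 5.83 and 5.37 with TGFbeta1.

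Of 31 epithelial junction and identity genes, 20 fell and none rose (23 and 0 adjusted over the list alone), with a median of -1.02. EPCAM fell from 69.3 ± 3.16 to 33.5 ± 1.79 FPKM, the epithelial transcription factor gene ELF3 from 36.8 ± 6.26 to 0.346 ± 0.237 and the tight junction gene TJP3 from 5.92 ± 1.0 to 0.065 ± 0.053 (SD, n = 3; adjusted p = 0.000638, 9.5e-05 and 0.000197). E-cadherin (CDH1) did not pass the test, at 42.7 ± 4.10 and 27.2 ± 6.94 FPKM (log2 change -0.66, adjusted p = 0.0771). Of 18 epidermal differentiation genes 14 fell and none rose (14 and 0 adjusted over the list alone), with a median of -1.99. The keratin KRT4 fell by 4.42 and the cornified envelope gene SPRR3 by 2.31. The 19 basal mammary markers went both ways, with 8 higher and 5 lower (8 and 6 adjusted over the list alone). The laminin chain gene LAMB3 rose by 2.05, ITGA6 by 1.07 and COL17A1 by 1.0. The basal keratin KRT5 fell from 1365 ± 84.8 to 873 ± 35.3 FPKM, and KRT14 did not pass the test (720.5 ± 212 and 565 ± 4.73 FPKM, adjusted p = 0.413). Of 8 luminal markers 3 fell (1 higher and 3 lower adjusted over the list alone), SLPI by 1.64. Of 11 transcription factors of epithelial-mesenchymal transition 4 rose (4 adjusted over the list alone). ETS1 rose by 0.85. SNAI2 had a log2 change of 1.44 and SNAI1 of 1.28, with adjusted p of 0.0356 and 0.0416. ZEB1 was at 0.817 ± 0.265 and 1.61 ± 0.121 FPKM (adjusted p = 0.0454). ZEB2 stayed under the filter, at 0.293 ± 0.032 and 0.563 ± 0.052. The SNAI2 call was lost without control 3 or any TGFbeta1 library (adjusted p of 0.0510 to 0.103). The SNAI1 call was lost without any control or TGFbeta1 3 (0.0920 to 0.116) and the ZEB1 call without any library but control 3 (0.0787 to 0.121), at a pseudocount of 0.1 (0.0650) and under quantile normalisation (0.0609). Without TGFbeta1 1, SNAI1 fell under the filter and was not tested.

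Of 29 growth factors and cytokines 14 rose and 3 fell (16 and 3 adjusted over the list alone). The inflammatory cytokine IL1B rose from 12.4 ± 0.054 to 73.2 ± 2.57 FPKM, ANGPTL4 from 15.7 ± 5.0 to 92.2 ± 4.94 and the chemokine CCL20 from 0.841 ± 0.380 to 3.09 ± 0.378 (SD, n = 3). Of 27 DNA replication and G1/S genes 9 fell (9 adjusted over the list alone), including the replicative helicase subunit MCM5 by 0.66, and of 26 mitosis genes none passed the test. The mitosis median was -0.03 and turned positive under all 3 other scalings. For the 4 tested cyclin-dependent kinase inhibitors, 1 fell: CDKN1C, by 0.74 (1 adjusted over the list alone), a call lost without control 1 (adjusted p = 0.0588) and with sums over transcripts listed in both sets (0.0661). CDKN1A was at 101 ± 83.2 and 140.3 ± 77.5 FPKM (adjusted p = 0.643), and CDKN2B was not analysed here. Among 20 cholesterol synthesis genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), MSMO1 by 0.89, and none fell under the 3 other scalings. Of 28 cytosolic ribosomal protein genes 5 fell (8 adjusted over the list alone), against 2 by median of ratios, 2 with an equal sum and 1 by quantiles, and the list lost its call under quantile normalisation (adjusted p = 0.0707) and with an estimated correlation (adjusted p = 0.199).

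Camera, a competitive gene set test, called neither the basal nor the luminal markers in the first set, and none of the remaining lists. Fry, which tests whether a list's genes move on balance one way, called basal markers (adjusted p = 7.4e-05), luminal markers (0.0227), interferon-stimulated genes (adjusted p = 0.00364), leukocyte, endothelial and erythroid markers (0.00477), oxidative phosphorylation genes (0.0116), histones (0.0135) and splicing regulators (0.0461). The median and mean log2 change differed in sign for the basal markers (0.14 and -0.207) and for the luminal markers (0.078 and -0.101). The interferon list gained a camera call without control 1 (adjusted p = 0.0359) and with genes under 5 FPKM left out (0.00178). Numbers higher and lower were 3 and 1 of 16 interferon-stimulated genes (4 and 2 adjusted over the list alone), 3 and 3 of 20 glycolysis and hypoxia genes (5 and 5), 4 and 1 of 20 unfolded protein response genes (5 and 3), and 6 and 4 of 19 oxidative stress genes (7 and 6). They were 2 and 1 of 15 early response genes (2 and 1), 0 and 1 of 14 splicing regulators (0 and 1), 0 and 4 of 24 oxidative phosphorylation genes (0 and 7), and 0 and 2 of 3 histone genes (0 and 2). The 4 oxidative phosphorylation genes became 2 by median of ratios, 1 with an equal sum and 1 by quantiles. Of 3 leukocyte, endothelial and erythroid markers, CSF1R rose by 1.01, CD14 fell by 1.28 and CD68 fell by 0.48, the last with a call lost without any library but TGFbeta1 2 (adjusted p of 0.0705 to 0.0920) and with libraries rescaled to an equal sum (0.0588). Only 2 mitochondrially encoded genes reached the filter. MT-CYB was listed at 2687, 2701 and 2381 FPKM in the controls and at 94.8, 0 and 98.0 with TGFbeta1 (adjusted p = 0.0501, and 0.000244 without TGFbeta1 2), while MT-ND5 was at 862 ± 33.1 and 884 ± 16.5 FPKM. Mitochondrial genes held 1.11% ± 0.089 of summed FPKM in the controls and 0.324% ± 0.024 with TGFbeta1 (SD, n = 3). Nearly all of this share was MT-CYB and MT-ND5, so its fall is that of MT-CYB, which did not pass the test. MT-ND2 was listed at 0 in all 3 controls.

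In all, 2186 of 10454 genes passed the first set's test, 941 higher and 1245 lower, and 533 of them changed by at least 1 on the log2 scale (277 higher and 256 lower). With libraries rescaled to an equal sum, the calls were 1146 higher and 849 lower, and the other 2 scalings also called more genes higher than lower (1074 and 984 by median of ratios, 1037 and 971 by quantiles). Leaving out control 1, control 2, TGFbeta1 1 or TGFbeta1 2 left 1390, 1437, 1365 and 1354 calls. With a preset correlation, camera called 16 of the 29 lists it could test. With an estimated correlation, 4 held: epithelial junction genes (adjusted p = 0.0422), mesenchymal markers, integrins and direct TGFbeta targets (0.0499 each). For the other lists named as called, the estimated-correlation adjusted p was 0.0638 for collagens and stromal markers, 0.0662 for epidermal differentiation, 0.13 for growth factors, the ID family and the ligand list, and 0.198 for contractile genes. It was 0.199 for ribosomal proteins, 0.248 for transcription factors, proteases and replication genes, and 0.426 for cholesterol synthesis.

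**Figure D1:**
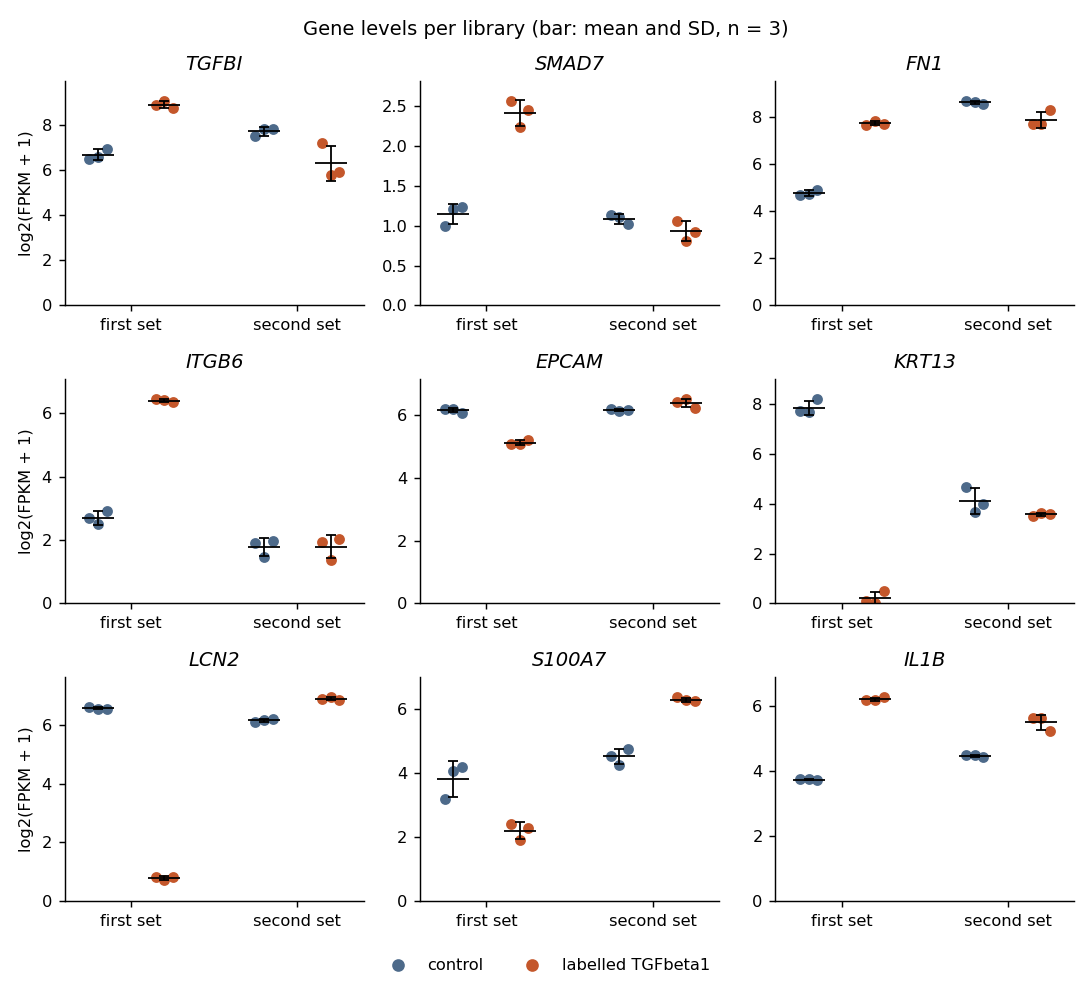
Levels of 9 genes as log2(FPKM + 1), with 1 point per library and bars for the mean and SD of 3 libraries, for control (blue) and TGFbeta1-labelled libraries (orange) of each set. TGFBI, SMAD7, FN1 and ITGB6 were higher and EPCAM, KRT13, LCN2 and S100A7 lower with TGFbeta1 in the first set, whereas in the second set LCN2 (log2 change 0.73), S100A7 (1.77) and IL1B (1.04) passed the test, all upward.

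In the second set, the libraries labelled TGFbeta1 had higher levels of epidermal differentiation genes than the controls, while SMAD7, ITGB6 and TGFBI, which had risen in the first set, did not pass the test. The antimicrobial protein gene S100A7 rose from 22.2 ± 3.86 to 77.1 ± 3.55 FPKM (SD, n = 3; log2 change 1.77, SE 0.13, adjusted p = 0.0179). The elastase inhibitor gene PI3 rose from 6.75 ± 0.697 to 22.3 ± 1.46 FPKM (log2 change 1.59, adjusted p = 0.0146). LCN2 rose from 70.4 ± 2.46 to 117 ± 3.24 FPKM. The serpin genes SERPINB3 and SERPINB4 rose by 1.24 and 1.26, and reads of these near-identical neighbours can be split between them by the assignment, so each value is uncertain. The sterol and steroid enzyme HSD17B7 rose by 1.45. The largest falls were those of the trafficking genes AP1M1, from 13.6 ± 0.778 to 2.80 ± 0.301 FPKM, STX6, from 20.98 ± 1.83 to 5.50 ± 0.790, and SNX6, from 52.8 ± 9.32 to 22.6 ± 1.43. They were followed by the matrix proteoglycan gene DCN, from 28.6 ± 1.97 to 12.4 ± 1.82, and the proton pump subunit ATP6V0C, from 73.0 ± 1.65 to 35.9 ± 2.43 (SD, n = 3). SMAD7 was at 1.12 ± 0.089 and 0.909 ± 0.170 FPKM (log2 change -0.16, adjusted p = 0.652) and ITGB6 at 2.45 ± 0.629 and 2.52 ± 0.801. FN1, at 397 ± 15.9 and 243 ± 61.9 FPKM, had a log2 change of -0.74 and an adjusted p of 0.226, which became 0.0267 without TGFbeta1 6 (log2 change -0.93). TGFBI, at 213 ± 27.2 and 87.2 ± 52.3 FPKM, had a log2 change of -1.42 and an adjusted p of 0.288, which became 0.0430 without TGFbeta1 4 (log2 change -1.87).

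Of 17 epidermal differentiation genes in the second set, 6 rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.54. Among 18 interferon-stimulated genes 2 rose, IFIT2 and IFIT3 (10 higher and 1 lower adjusted over the list alone), with a median of 0.42. IFIT2 was chosen after its value was seen. In the other lists at most 2 members passed the test over all genes, and 16 of their set tests passed, 10 with medians above 0 and 6 with medians below 0. With an estimated correlation 8 lists held, each at an adjusted p of 0.0486. Their medians were 0.54 for epidermal differentiation, 0.42 for interferon-stimulated genes, 0.26 for epithelial junctions, 0.17 for cholesterol synthesis, 0.11 for the unfolded protein response, -0.23 for mesenchymal markers, -0.36 for collagens and -0.86 for stromal markers. Basal markers lost theirs without TGFbeta1 5 (adjusted p = 0.0619) and mitochondrial genes without control 5 (0.263) or TGFbeta1 4 (0.13), neither of which held with an estimated correlation (0.102 and 0.557). Oxidative phosphorylation genes gained a call without control 6 (0.0327). The interferon list lost its call when genes under 5 FPKM were left out (adjusted p = 0.0889). It was 1 of 5 lists that lost their call under another setting of the processing. The direct targets had 1 fall, CTGF (log2 change -0.61, chosen after its value was seen), a median of -0.08 and an adjusted p of 0.0425, which rose to between 0.0584 and 0.227 without control 5 or any of the TGFbeta1 libraries. Its adjusted p was 0.200 with an estimated correlation.

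In all, 34 of 10579 genes passed in the second set, 18 higher and 16 lower, and 1182 had an unadjusted p under 0.05. Without control 4 limma called 0 genes, with 973 at an unadjusted p under 0.05, so each of the 34 calls was lost. The counts were 5 without control 5, 6 without control 6, 11 without TGFbeta1 4 and 16 without TGFbeta1 6, and 17 with libraries rescaled to an equal sum. Mitochondrial genes, of which 13 were tested in this set, held 8.33% ± 0.291 of summed FPKM in the controls and 8.71% ± 0.277 in the TGFbeta1-labelled libraries (SD, n = 3). The authors' deposited table for this set, tested per transcript, had 28 of 29204 transcripts at a q-value under 0.05, 12 higher and 16 lower.

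**Figure D2:**
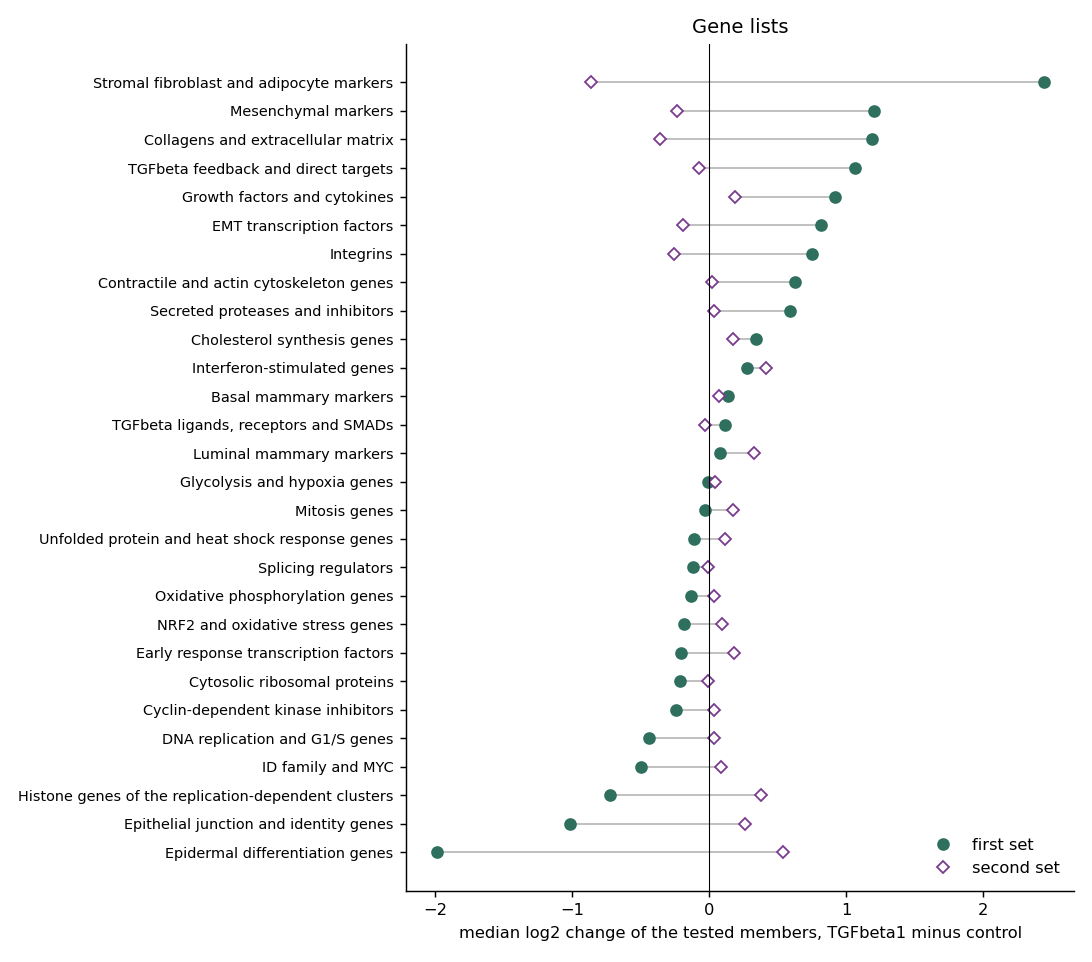
Median log2 change, TGFbeta1 minus control, of the tested members of 28 gene lists in the first set (filled circles) and the second set (open diamonds). Collagens lay at 1.18 and -0.36, mesenchymal markers at 1.2 and -0.23, epithelial junction genes at -1.02 and 0.26, and epidermal differentiation genes at -1.99 and 0.54. The signs of the mitosis and the glycolysis and hypoxia medians in the first set, and of the contractile and splicing medians in the second, depend on the scaling.

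The effect of TGFbeta1 differed between the sets for 1436 of 10548 genes by the interaction test, with the second set's change above the first's for 797 and below it for 639. The largest differences upward were those of KRT13 (7.10), MT-CYB (7.0), PSCA (6.77), LCN2 (6.50) and S100P (6.02), given as the second set's log2 change minus the first's. The largest downward were those of COL5A1 (-4.09), PDPN (-4.06), ADAM19 (-3.91), TGM2 (-3.83) and FN1 (-3.70). SMAD7 differed by -1.42 (SE 0.16, adjusted p = 0.000241), VIM by -1.03 (adjusted p = 0.00407) and EPCAM by 1.25 (adjusted p = 5.3e-05). The MT-CYB call (adjusted p = 0.0412) was lost without any control or without any TGFbeta1 library of the second set. By lists, 20 of 22 collagen and matrix genes, 13 of 16 mesenchymal markers and 13 of 21 direct targets had a lower change in the second set. A higher change was found for 19 of 30 epithelial junction genes and 14 of 18 epidermal differentiation genes. Camera called 16 lists for the difference, and 9 held with an estimated correlation. Rescaling the libraries to an equal sum moved the median difference of all genes by -0.10 and gave 523 higher and 769 lower calls. Each difference named here was larger than that shift.

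Of 9990 genes tested in both sets, 2043 were called in the first and 30 in the second, and 18 in both. Direction was the same for 5 of them, IL1B, C10orf10 and MT2A upward and ATP6V0C and RGS2 downward, where independent lists would share 1.28 upward and 1.78 downward. C10orf10 and MT2A were chosen after their values were seen. Direction was opposite for 13, where independent lists would share 1.78 that fell in the first set and rose in the second, and 1.28 of the reverse. Of these, 9 had fallen in the first set and risen in the second, including LCN2, PI3, S100A7 and SERPINB3, and 4 had risen in the first and fallen in the second, including DCN. In the first set the S100A7 call was lost without control 2 (adjusted p = 0.0602), TGFbeta1 2 (0.0604) or TGFbeta1 3 (0.0518), and the ATP6V0C call without any library but TGFbeta1 3 (0.0514 to 0.0712). Being called in the first set and in the second went together regardless of direction (Fisher's exact test, two-sided, p = 2.48e-06). The test treats genes as independent, which they are not, so its p is only descriptive. Across all 9990 genes, which are not independent replicates, the changes correlated at r = -0.061 and Spearman rho = -0.039.

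**Figure D3:**
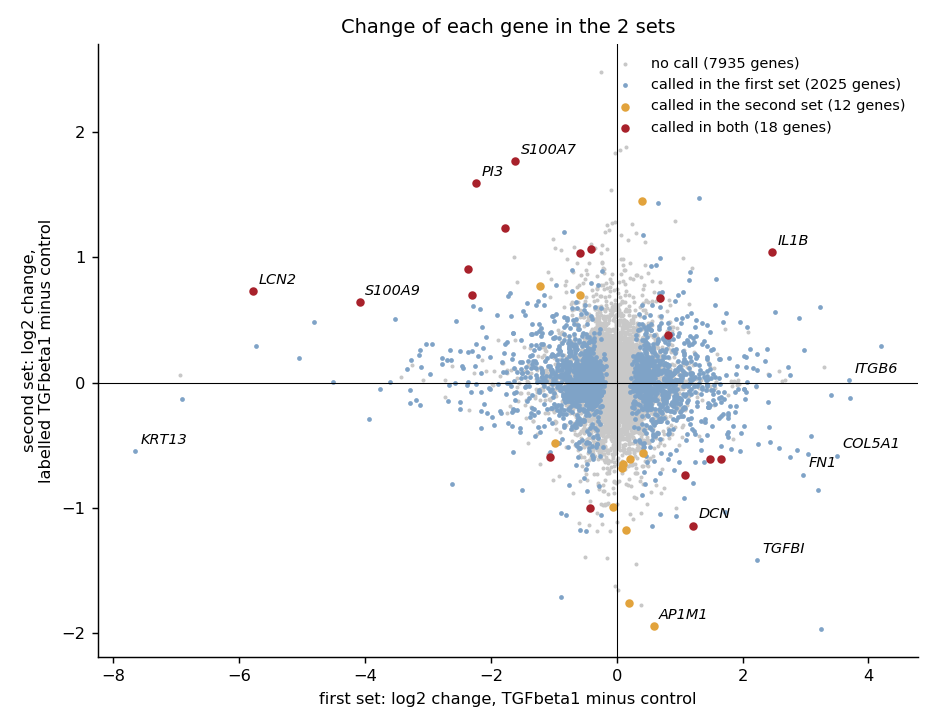
Log2 change of each of 9990 genes in the first set (x axis) and the second set (y axis), TGFbeta1 minus control, coloured by where the gene was called. Of the 18 genes called in both sets, 5 had the same sign and 13 opposite signs, with IL1B at 2.47 and 1.04 and LCN2 at -5.77 and 0.73.

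With both sets in 1 model and the set as a term, 53 of 10548 genes were called, 33 higher and 20 lower, each in the same direction in both sets. This model fits 1 effect to both sets, so a gene with opposite changes was unlikely to be called. The shared direction is therefore largely set by the model and is no separate evidence of agreement. The inflammatory genes IL1B (log2 change 1.75, SE 0.23, adjusted p = 0.0114) and CCL20 (1.03, adjusted p = 0.0114) rose, as did the immediate early transcription factor JUN (0.62, adjusted p = 0.00759), the coiled-coil protein gene TMCC1 (0.84, adjusted p = 0.00759), the growth factor-like gene IGFL1 (0.89, adjusted p = 0.0146) and the endoplasmic reticulum chaperone gene HSPA5 (0.44, adjusted p = 0.0146). The interferon-stimulated gene IFIT3 rose by 0.81 (adjusted p = 0.0114), a call lost at a pseudocount of 0.1. RGS2, a regulator of G protein signalling, fell from 136 ± 13.0 to 64.1 ± 3.48 FPKM in the first set and from 56.2 ± 3.28 to 36.7 ± 1.76 in the second (SD, n = 3; log2 change -0.83, adjusted p = 0.00759). These 8 were the named genes whose calls held whichever library was left out. The other named calls were lost without at least 1 library, ATP6V0C, FEZ1 and FLVCR2 without TGFbeta1 2 alone (adjusted p = 0.0510, 0.0510 and 0.0520): higher, TNFAIP3, IRAK2, ZC3H12A, AKR1C2, FEZ1 and COL8A1 were among them, and lower, ATP6V0C, FLVCR2, ADAMTSL4, WISP2, SYT8, SPTLC3, BCAM and SLC16A14. ATP6V1B1, also lower, was listed at 0 FPKM in all 3 TGFbeta1 libraries of the first set. FN1 (1.11, adjusted p = 0.302) and VIM (0.36, adjusted p = 0.289) were not called, and the change of both differed between the sets by the interaction test.

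Of the 30 lists, camera called 13 over both sets, with growth factors and cytokines leading (2 of 29 genes higher, 14 higher and 2 lower adjusted over the list alone, median 0.58). The interferon list, with 1 of 18 genes higher (5 adjusted over the list alone), a median of 0.27 and an adjusted p of 0.000155, held with an estimated correlation (adjusted p = 0.0442). The other 12 had adjusted p of 0.147 to 0.556 with an estimated correlation. Medians had opposite signs in the 2 sets for direct targets (1.06 and -0.08), mesenchymal markers, collagens and integrins. They also did for epithelial junction, epidermal differentiation, replication and mitosis genes. For these lists a call over both sets is not a shared response. Signs were the same for growth factors, interferon-stimulated, contractile, cholesterol synthesis and ribosomal protein genes. The mitosis and contractile signs depend on the scaling. The count of 53 genes was 30 at a pseudocount of 0.1, 24, 23 and 31 without controls 1, 2 and 3, and 26, 10, 26, 35 and 82 without TGFbeta1 1, 2, 3, 4 and 6.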

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

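The tests of precision, of exchanged labels and of the second set's controls were chosen only after the result was seen. Set tests of the difference and sums over transcripts listed in both sets were also added after seeing the data. TGFbeta1 had a different effect in the 2 sets for 1436 genes by the interaction test. Of 100 splits of the libraries within each set, 1 gave as many, the real split. The highest other gave 1371, and the 8 other splits that kept the first set's own groups gave 1094 to 1371, against at most 18 with another grouping of the first set. These splits argue only against groups set by chance in both sets at once. The count mostly follows the first set's own groups, and the 10 splits of that set alone are too few for a share under 0.05. The 8 other splits that kept those groups are also too few. The splits therefore do not exclude chance for the difference between the sets.

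Differences are the second set's log2 change minus the first's. Genes with a lower change in the second set were COL5A1 (-4.09), PDPN (-4.06), ADAM19 (-3.91), TGM2 (-3.83), FN1 (-3.70), ITGB6 (-3.68), TGFBI (-3.65), AP1M1 (-2.53), COL1A1 (-2.4), DCN (-2.35), SNAI2 (-1.64), SMAD7 (-1.42), SNX6 (-1.32), VIM (-1.03), CDH2 (-1.03) and ATP6V0C (-0.58). Genes with a higher change were KRT13 (7.10), MT-CYB (7.0), PSCA (6.77), LCN2 (6.50), S100P (6.02), A2ML1 (5.25), PI3 (3.82), S100A7 (3.38), SERPINB3 (3.02), SERPINB4 (1.25), EPCAM (1.25), ID1 (1.23), HSD17B7 (1.05), KRT5 (0.70) and ID3 (0.66). The MT-CYB call was lost without any control (adjusted p = 0.0680 to 0.0800) and without TGFbeta1 4, 5 or 6 (0.0757 to 0.0786).

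By lists, the median difference was -2.40 for stromal markers, -1.33 for collagens, -1.25 for mesenchymal markers, -0.91 for direct TGFbeta targets, -0.90 for integrins, -0.81 for transcription factors and -0.61 for contractile genes. It was 1.27 for epithelial junctions and 2.71 for epidermal differentiation. For the other lists the call was lost with an estimated correlation. Their medians, with the adjusted p with an estimated correlation, were -0.45 for growth factors (adjusted p = 0.190), -0.30 for ligands and receptors (adjusted p = 0.0907), 0.66 for the ID family and MYC (adjusted p = 0.0949) and 0.68 for histones (adjusted p = 0.0738). They were 0.425 for replication genes (adjusted p = 0.121), 0.26 for mitosis genes (adjusted p = 0.329) and 0.16 for ribosomal proteins (adjusted p = 0.435). With libraries rescaled to an equal sum the medians were -0.816 for growth factors, 1.025 for histones, 0.155 for mitosis genes and 0.046 for ribosomal proteins. The last 2 were 0.155 and 0.047 by quantiles, and that of ribosomal proteins was 0.1 by median of ratios.

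Most of the first set's response was not seen in the second set, where 5 of its calls were called with the same sign. Low precision is argued against, since for 96% of 455 genes with a change of at least 1 in the first set the second set's 95% interval excluded that change, and so are different transcripts behind the gene sums, since 1137 genes still differed over shared transcripts. An equal response under exchanged labels is argued against by a slope of -0.0315 across the first set's calls. An exchange of 1 library per group that hid an equal response is argued against by a highest slope of 0.0367 over the other splits. A much weaker response hidden in this way would also give a small slope and is not excluded. For second-set controls already in the treated state, the difference between the sets' controls was set against the first set's change. The slope was 0.3006 to 0.3277, which argues against such controls as the whole cause. It was above 0 with each choice of control, so a partial contribution stays open. With the second set's labels turned round, 227 genes were called over both sets (114 higher and 113 lower) against 53 as labelled, so exchanged labels with a weaker response may account for the opposite signs, although only 52.9% of 2043 first-set calls, and 58.6% of the 324 of them with an unadjusted p under 0.05 in the second set, had the opposite sign there. These cannot be told apart from a real opposite effect, which gives the same count, and a difference in dose, time or cells was not tested.

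By the median of their list, epidermal differentiation genes fell in the first set and rose in the second. Of the 17 members tested in the second set, 6 were called, among them LCN2, PI3 and S100A7, and 11 were not. The keratin KRT13, the largest fall of the first set, was not among the calls, so the rise does not hold for each member. A single second-set library is argued against, since the list's median change there stayed at 0.4548 or more, the lowest being without TGFbeta1 4. Unequal scaling is argued against by a lowest median of 0.5251 under 3 other scalings. The other 9 splits of the second set gave medians of 0.11 to 0.24 in absolute size, with their signs left out. Exchanged labels, as above, may also give this pattern and stay open.

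For the first set, 1 of the 10 splits of its 6 libraries gave as many genes, the real one with 2186 against at most 8 in the others. For the second set it was also 1 of 10, with 34 against at most 9. These splits are too few for a share under 0.05. Over both sets 2 of 100 splits gave at least 53 genes, the real one and that with the second set's labels turned, with 227. Splits with another grouping of the first set gave at most 1. The 8 other splits that kept the first set's own groups had a median of 0.5 and are too few for a share under 0.05. The splits therefore argue only against groups set by chance in both sets at once. They do not exclude chance for the agreement between the sets. For gene lists 10 of 100 splits gave at least the real 13, the highest being 18, and chance cannot be excluded. Splits with another grouping of the first set gave up to 13 lists. The counts of lists called in each set alone were not set against splits, so chance is not excluded for them either.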

How the results depend on the processing

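Tests per transcript and gene sums over shared transcripts were chosen only after seeing the data. No named gene that was called changed sign. In the first set the 2186 calls became 533 with a log2 change of at least 1, 889 genes by tests per transcript, 1211 with a replicate block (1156 of them among the 2186) and 1354 to 2030 with 1 library left out. The other settings gave 1584 to 2568. In the second set the 34 became 17 with an equal sum per library, 20 without trend, 14 with a log2 change of at least 1 and 0 to 23 with 1 library left out. With a replicate block limma called 0, with 1134 genes at an unadjusted p under 0.05. Over both sets the 53 became 30 at a pseudocount of 0.1, 5 with a log2 change of at least 1, 5 when called in each set alone with the same sign, and 10 to 82 with 1 library left out. With a replicate block limma called 0, with 1422 at an unadjusted p under 0.05. The 1436 differences became 561 with a log2 change of at least 1, 1207 to 1501 with 1 library left out and 1050 to 1527 under the others, including 1114 with the block. The 5 calls shared with the same sign became 9 at an adjusted p under 0.1, 1 with a log2 change of at least 1 and 0 with the block. The 13 lists became 1 with an estimated correlation and 4 by fry, and stayed at 12 to 13 with 1 library left out. Apart from the stricter thresholds, which leave fewer genes by construction, the cause was not tested. The labels do not say whether libraries with equal replicate numbers share a culture or day. Deviations of same-numbered libraries correlated at 0.007 to 0.046 across genes, and all but replicate 3 correlated best with their own number. A shared origin of same-numbered libraries is therefore not excluded. Of the named genes called, some fell under the filter in a left-out fit and were not tested there. The left-out fits in which a gene was tested all kept the call for 82 of 105 in the first set and 0 of 15 in the second. They did so for 8 of 24 over both and 71 of 83 for the difference. Depth is unknown, so counting error could not be separated from the spread between libraries.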

Other observations

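The tests of gene totals were chosen only after the result was seen, as were the tests per transcript and the transcripts named. In the first set 1003 of 18113 transcripts were called by limma, 490 higher and 513 lower, and 9 genes had transcripts called both ways. DIAPH1, a formin that nucleates actin filaments, had ENST00000389054.7_1 lower, at 53.6 ± 10.5 and 10.8 ± 2.51 FPKM, and ENST00000518047.5_1 higher, at 7.89 ± 2.03 and 46.03 ± 6.80 (SD, n = 3, control and TGFbeta1), with a gene total of 65.6 and 71.5 FPKM that did not pass the test (adjusted p = 0.410). TFPI, an inhibitor of coagulation, had ENST00000233156.7_1 at 7.58 ± 1.2 and 0.777 ± 0.151 FPKM and ENST00000426055.5_1 at 9.87 ± 1.37 and 22.6 ± 0.823. LIMA1, an actin-binding protein gene whose total rose, had ENST00000341247.8_1 fall from 3.17 ± 1.45 to 0.172 ± 0.119 FPKM while ENST00000552823.5_1 rose from 23.4 ± 0.679 to 50.8 ± 1.77. Transcripts separated by at least 4-fold with a nearly equal gene total numbered 26 in the real split and 28 in the highest other, so such separations were no more common than in another grouping. Of the 10 splits of the 6 libraries, 1 gave as many transcripts, the real one, with at most 10 in the others, which are too few for a share under 0.05.

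In the second set 45 of 20392 transcripts were called, and 5 genes (VIM, CRK, KDM3A, SPAG1 and ACIN1) had transcripts called both ways. VIM had ENST00000224237.9_1 at 602 ± 63.2 and 45.5 ± 20.1 FPKM and ENST00000544301.6_2 at 0.038 ± 0.065 and 494 ± 40.7 (SD, n = 3; adjusted p = 0.0337 and 1.27e-05). Of 10 splits 1 gave as many calls, with 36 in the highest other, too few splits for a share under 0.05. Transcripts separated by at least 4-fold with a nearly equal gene total numbered 42 in the real split and 59 in the highest other, a ratio of 0.712, so unstable assignment of reads to transcripts may account for such exchanges. A change of the whole gene is argued against for VIM, SPAG1 and KDM3A, whose totals differed by at most 1.192 times. The totals of CRK and ACIN1 differed by 1.592 times or more. That of CRK fell and passed the test (log2 change -0.65, adjusted p = 0.038), a call lost without control 4. That of ACIN1 did not pass (log2 change 0.89, adjusted p = 0.119). For both genes a change of the whole gene beside the exchange stays open. As the whole cause it is argued against, since their transcripts moved in opposite directions. Those of CRK went from 37.3 ± 1.17 to 4.30 ± 0.443 FPKM and from 2.02 ± 0.218 to 19.8 ± 1.28. Those of ACIN1 went from 10.5 ± 1.84 to 2.73 ± 0.254 and from 1.28 ± 0.165 to 16.2 ± 0.774 (SD, n = 3). No biological explanation was tested.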
